A study of Mus musculus with 12 samples.

How the data were processed

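Total RNA of sorted splenic B cells was labelled with biotin and hybridized to Illumina mouse bead arrays, 12 arrays in 4 groups of 3 named naive, early GC, late GC and memory. The extraction protocol describes the sort of GC B cells on days 8 and 18 only, and the assignment of day 8 to early and day 18 to late is a reading of the group names. The authors processed the arrays with lumi, whose version and settings were not given. The deposited intensity table is named non-normalized, but the sorted values of its 12 columns had a median spread of 0.0332% of their mean (at most 1.63%), so these intensities had been quantile normalized. They ran from 97.25 to 41986, a linear scale, and the lowest value was read as a sign that background had not been subtracted, which was not tested. The intensities equalled the series value table, with a largest difference of 0. The detection p-value of each probe and array was deposited per the file headers, and was read as the share of negative control probes at least as bright, since the values move in steps of 1 in 936. How it was made was not stated.

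Background was corrected and arrays were normalized with neqc of limma 3.58.1 in R 4.3.3, with the background's mean and SD inferred from the detection p-values, an offset of 16 and quantile normalization, and values were taken as log2. Gene symbols came from the platform annotation, which gave 1 symbol for 34885 of 45281 probes, several for 18 and none for 10378. Of the probes with 1 symbol, 34807 were looked up by Entrez identifier in the RefSeq gene table of GRCm38.p6, used for names only, and 0 symbols changed. Probes with 1 symbol and a detection p-value below 0.01 on at least 3 of the 12 arrays were kept (12224 probes), and the probe with the highest mean over the arrays stood for each of 7988 genes, 2983 of which had more than 1 such probe. The number of arrays, 3 per group, limits the precision, and the median SE of a log2 difference was 0.158.

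All comparisons used one limma fit of group means on the 12 arrays (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. The main comparisons were late against early GC, early GC against naive, late GC against memory and memory against naive, with late GC against naive, memory against early GC and the difference between the within-chip comparisons besides. Chip was not a term of the fit, since each group lies on 1 chip. For a gene detected on 0 arrays of one group, the fold is a lower bound. It sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the array's lowest detected signal and its own signal. Gene lists written from general knowledge of B cell biology and of other cell types were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, which was so for 25 lists, with adjustment over lists within a comparison. Camera with an estimated correlation and fry, with statmod 1.5.0 installed, were the alternatives.

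Genes were named by a rule. It took the 8 largest rises and the 8 largest falls of each comparison among genes past the threshold, detected on all arrays of the higher group, with array values that did not overlap between the groups (not asked for the difference of differences) and without clone-type symbols. It added the sort and state genes Fas, Cd38, Aicda, Bcl6, Prdm1, Myc, Mki67, Ccr6, Ighd and Sell, and up to 4 members with the smallest p-value of each list described. Immunoglobulin, histone and other multigene family members were named as uncertain. The groups, the comparisons and their tests, the gene lists tested with camera, the naming rule and the alternatives were fixed before the data were examined. The tests of explanations, and a list of further neutrophil genes used in one of them, were written after that.

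The procedure was tested on simulated data with 200 changed genes per comparison among 7988. At a log2 change of 1 it recovered 94.0% for late against early GC, 92.5% for early GC against naive, 92.5% for late GC against memory and 94.0% for memory against naive. At a log2 change of 0.5 the shares were 19.4%, 31.3%, 26.9% and 23.9% in the same order. The share of false calls was 7.84%, 6.88%, 6.41% and 3.97%. The simulated noise was normal and independent between genes, with the SD of the fit, and held no chip effect and no detection floor. The data gave more changed genes, 1818 to 4808 in these comparisons, so the shares need not carry over to them.

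The alternatives were the deposited values without further correction, no background correction, median scaling, cyclic loess, an offset of 50, no filter on dim probes, detection on all 12 arrays, the mean of a gene's probes, every probe tested, eBayes with trend and robust, array weights, only the 6 arrays compared, the replicate number as a block, an adjusted p threshold of 0.01, a 2-fold minimum, and leaving out each array in turn. Probes without a symbol were tested apart, 2025 of which passed the detection filter. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.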

Results

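Genome-wide transcript levels were measured on Illumina mouse bead arrays in splenic B cells of 4 stages, with 3 arrays per stage. B cells carrying the B1-8i heavy chain, which pairs with lambda light chains to bind the hapten NP, were transferred into BALB/cJ mice with the AM14 transgene and the Vκ8R light chain. The recipients were immunized with NP-CGG, the hapten coupled to chicken gamma globulin. Germinal centre (GC) B cells, which proliferate and mutate their receptors after immunization, were sorted as live CD19+ NP-binding cells lacking kappa light chain and CD38 and expressing CD95. They were taken on day 8 and day 18, read here as the early and the late GC groups. Naive and memory B cells were the other 2 groups, and the labels do not describe their sort. The study's title asks how the GC changes over time in its output of memory and plasma cells, so the late GC was set against the early GC first. Nothing in the labels says that the 3 arrays of a group came from separate animals, and if they did not, the p-values measure only the spread between these samples.

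Between 11679 and 13376 of 45281 probes were detected per array, and 7988 genes were tested. Replicate arrays correlated at r = 0.98 to 0.99 across genes, which are not independent replicates. The first principal component held 70.5% of the variance and parted both GC groups from naive and memory cells, and the second held 13.8%. Naive and early GC samples shared one chip, and late GC and memory samples shared the other. The comparisons of early GC with naive and of late GC with memory were therefore made within a chip, whereas for late against early GC and for memory against naive, chip and group cannot be told apart. Within each chip the groups lay at different array positions, naive and late GC at A to C and early GC and memory at D to F. Array position and group therefore cannot be told apart in either within-chip comparison taken alone. Differences below are on the log2 scale of background-corrected intensity ± SE of the limma fit, with 3 arrays per group, and p-values are limma's after Benjamini-Hochberg adjustment. "At least" marks a fold against a group in which the probe was not above background on any array. Where it was detected on 1 or 2 of the 3 arrays of the dimmer group, the difference is the fitted value, which depends on the background and is no bound, and detection on 1 array is stated.

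**Figure D1:**
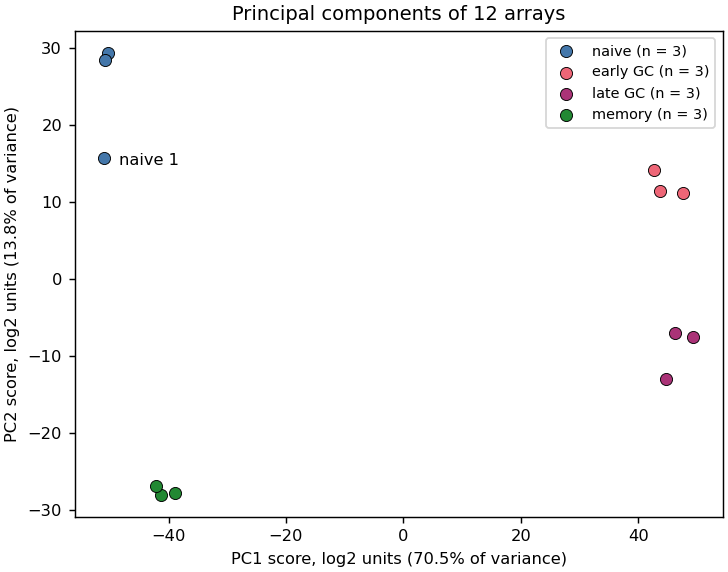
Scores of the 12 arrays on the first 2 principal components of log2 intensity over 7988 genes, one point per array and one colour per group. The GC arrays lie at PC1 scores of 42.7 to 49.3 and the naive and memory arrays at -51.0 to -38.8, and naive replicate 1 lies at 15.8 on PC2 against 29.3 and 28.4 for the other naive arrays.

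The sort markers and state genes were read first. Fas, which encodes CD95, had a mean log2 intensity of 7.36 ± 0.29 (SD, n = 3) in naive, 10.40 ± 0.09 in early GC, 10.97 ± 0.06 in late GC and 9.68 ± 0.41 in memory cells. Bcl6, the transcription factor required for GC formation, stood at 11.12 ± 0.11, 12.35 ± 0.09, 12.71 ± 0.08 and 10.34 ± 0.13 in the same order. Ccr6, a chemokine receptor of resting B cells, stood at 12.91 ± 0.11 in naive and 12.74 ± 0.04 in memory cells, against 7.89 ± 0.50 in early and 5.82 ± 0.23 in late GC cells. Myc, the growth-promoting transcription factor, lay near background, between 5.30 ± 0.38 in late GC and 6.35 ± 0.22 in naive cells. Prdm1, the plasma cell regulator, had 2 probes and was detected on 0 of the 12 arrays. Cd38, Aicda, Mki67, Ighd, Sell, Cd19, Igkc and Iglc1 were not listed in the annotation used here.

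**Figure D2:**
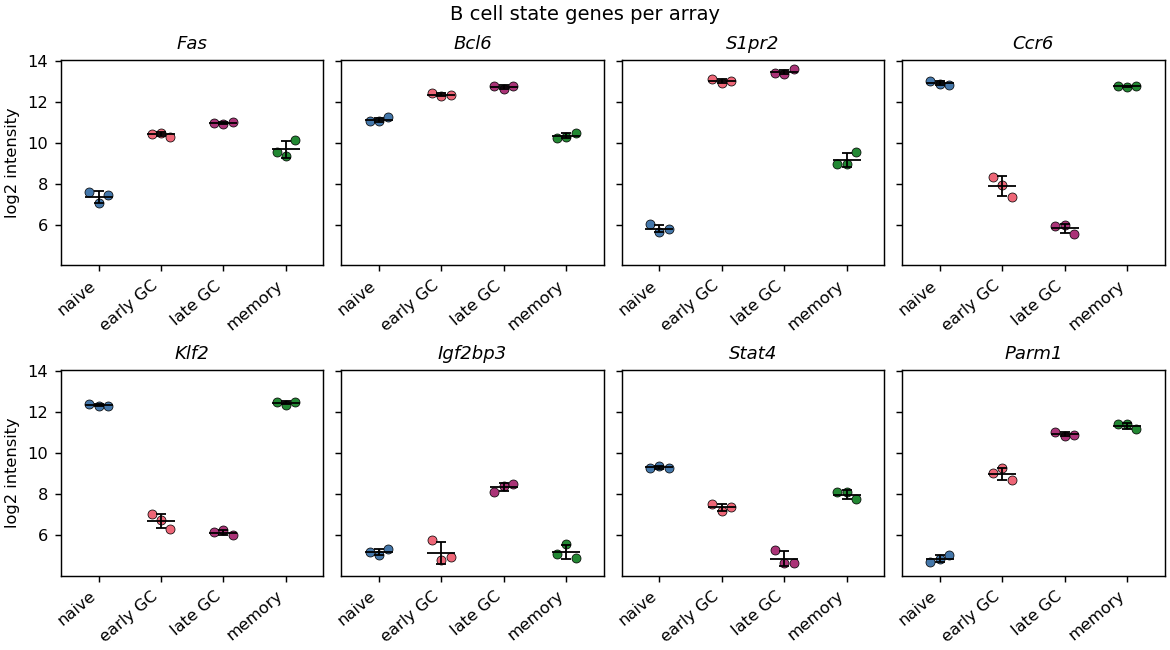
Log2 intensity of 8 genes on each of the 12 arrays (points), with the mean and SD of the 3 arrays per group (bars). Ccr6 and Klf2 are above 12 on all naive and memory arrays and below 9 on all GC arrays, whereas Igf2bp3 is raised in late GC and Stat4 is lowest there.

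Late GC B cells were compared with early GC B cells to see how the GC population differed between the time points. Late GC cells expressed more Igf2bp3, an RNA-binding protein of fetal and proliferating cells, by 3.19 ± 0.24 (adjusted p = 4.97e-06). They also expressed more Gnaz, a G protein alpha subunit, by 3.11 ± 0.27, Etl4 by 3.08 ± 0.23, Nrep by 2.78 ± 0.19 and Chrna9 by 2.75 ± 0.17. Igf2bp3, Etl4 and Chrna9 were detected on 1 of 3 early GC arrays. Fam135a was at least 7.08-fold, Ntng2 at least 4.01-fold and Snurf at least 3.71-fold higher. Stat4, which transmits interleukin 12 signals, was at least 3.77-fold lower (adjusted p = 3.65e-06), Aldh4a1 at least 3.36-fold and Dok2, an adaptor that restrains kinase signalling, at least 2.68-fold lower. Sh2d2a, detected on 1 late GC array, stood at -2.46 ± 0.16, Slco4a1 at -2.36 ± 0.12, the chromatin organizer Satb1 at -2.10 ± 0.18 on its brightest probe (a dimmer probe had the other sign), and Ccr6 at -2.06 ± 0.20, and Cfp, which encodes properdin, was 3.99-fold lower. The adjusted p of these 16 genes was at most 3.84e-05. Stat4, Sh2d2a and Satb1 were also lower in memory (means 7.97, 8.05 and 10.89) than in naive cells (9.30, 9.89 and 12.62), across the same chips. Dok2 went the other way (10.3 in memory, 9.4 in naive), and Slco4a1, Aldh4a1, Ccr6 and Cfp differed less.

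Of the 25 gene lists tested between late and early GC, camera with a preset correlation called 9. Camera called 0 of them with an estimated correlation, the lowest being adjusted p = 0.29 with an estimated correlation, whereas fry called 10 of the 25. Counts of list members are over all genes tested, and those adjusted over the list alone were the same unless given. In the germinal centre programme 6 of 15 tested members rose, 1 fell and 8 did not pass, against 7 and 1 adjusted over the list alone (median 0.31, adjusted p = 0.024). Basp1 rose by 1.73 ± 0.22, Efnb1 by 0.88 ± 0.19 and Gna13, which confines B cells to the GC, by 0.63 ± 0.13, while Cd93 was at least 1.60-fold lower. Across the same chips, memory against naive, Efnb1 rose as well, by 1.80 ± 0.19, whereas Bcl6 stood at -0.77 ± 0.12. Bcl6 differed by 0.36 ± 0.12 (adjusted p = 0.040) and Fas by 0.56 ± 0.19 (adjusted p = 0.0496), and the calls were lost in 6 and 8 of the 12 runs that left out 1 array, with adjusted p up to 0.118 for Bcl6 without late replicate 1 and 0.125 for Fas without early replicate 3. In B cell receptor signalling 6 of 24 members rose and 1 fell, against 7 and 1 adjusted over the list alone (median 0.25). The phosphatase gene Inpp5d rose by 1.03 ± 0.16 and the kinase gene Pik3cd by 0.88 ± 0.15, while Cd72, an inhibitory coreceptor, fell by 1.07 ± 0.11. Memory against naive cells gave 0.72 ± 0.16 for Inpp5d and -1.06 ± 0.11 for Cd72, as a shared chip effect would also give. Ptprc, which encodes CD45, stood 0.75 ± 0.14 higher on its brightest probe and -0.09 on the mean of its probes, so its direction is uncertain. Glycolysis genes rose in 5 of 16 cases and fell in 0 (median 0.20), among them Pdk1 by 1.17 ± 0.23 (detected on 1 early GC array) and Aldoa by 0.92 ± 0.15. Aldoa was also higher in memory than in naive cells, by 0.78 ± 0.15, across the same chips. In MHC class II presentation 2 of 15 members rose (median 0.26), against 798 of 7988 among all genes tested. Ifi30 stood at 0.62 ± 0.13 (0.23 and not past the threshold on the mean of its probes). H2-DMb1 stood at 0.53 ± 0.14, a call lost without early replicate 3 (adjusted p = 0.066) and without early replicate 1, late replicate 1 or late replicate 2. Among cytokine and costimulatory receptors and ligands 8 of 27 rose and 1 fell (median 0.09), with Tnfsf9 at least 1.49-fold higher and Il10ra at -1.58 ± 0.21.

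In DNA replication and S phase 10 of 27 members fell and 1 rose (median -0.24, adjusted p = 0.024), with Gins1 at -0.79 ± 0.20, Cdc6 at -0.57 ± 0.15 and Tk1 at -0.55 ± 0.14 (-0.30, adjusted p = 0.163, on the mean of its probes). Tk1 went the other way in memory against naive cells, at 0.75 ± 0.14. The call of Cdc6 was lost without late replicate 3 (adjusted p = 0.062) and without early replicate 3 (0.061), and those of Gins1 (0.067), Tk1 (0.070), Aurkb (0.059) and Ndufc1 (0.057) without late replicate 1. In G2/M and mitosis 4 of 21 fell and 1 rose over all genes tested, against 9 and 1 adjusted over the list alone (median -0.40). Anln stood at -0.80 ± 0.18 and Aurkb at -0.51 ± 0.13, while Ube2c, which acts in mitotic exit, was at least 1.13-fold higher. Oxidative phosphorylation genes fell in 10 of 33 cases and rose in 0 (median -0.23), among them Ndufc1 at -0.56 ± 0.14 and Atp5b at -0.47 ± 0.11. In the interferon response list 5 of 21 fell and 0 rose, against 7 and 0 adjusted over the list alone (median -0.32), led by Ifit3 at -1.80 ± 0.16, Ifit2 at -1.35 ± 0.22 (detected on 1 late GC array) and Usp18 at -1.15 ± 0.25. Leaving out 1 array, camera with a preset correlation called as few as 3 lists without early replicate 3 and 4 without late replicate 3. The germinal centre and B cell receptor lists were called in 12 of 12 such runs. The highest adjusted p was 0.10 for S phase, 0.11 for G2/M, 0.11 for MHC class II and 0.11 for oxidative phosphorylation without early replicate 3, 0.10 for glycolysis and 0.10 for interferon response without late replicate 3, and 0.19 for the cytokine list without late replicate 1.

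Lists of memory and plasma cell genes were not called between late and early GC. They were read in cells sorted as GC B cells, so they do not measure how many memory or plasma cells the GC put out. The memory list also holds genes of resting cells, such as Ccr6 (12.91 in naive, 12.74 in memory). In the memory B cell list 4 of 20 members rose and 6 fell, against 4 and 7 adjusted over the list alone (median -0.31, mean -0.09, adjusted p = 0.88). Zbtb20 rose by 2.13 ± 0.17, Nt5e, which encodes CD73, by 1.81 ± 0.19 and Bmpr1a by at least 1.94-fold, while Ccr6 fell as above. Zbtb20 was also higher in memory than in naive cells, by 3.55 ± 0.17, across the same chips. In the plasma cell programme 3 of 15 rose and 2 fell, against 3 and 4 adjusted over the list alone (median -0.06, mean 0.01, adjusted p = 0.97). The elongation factor gene Ell2 was at least 1.80-fold higher, Slamf7 stood at 0.53 ± 0.13 on its brightest probe (another had the other sign), Ssr4 at -0.54 ± 0.12 and Derl3 at -0.52 ± 0.16. Light zone and CD40/NF-kB activation genes rose in 5 and fell in 3 of 26 cases, or 7 and 3 adjusted over the list alone (adjusted p = 0.16), with Egr1 at 1.41 ± 0.21. Dark zone genes rose in 3 and fell in 2 of 14 cases, or 4 and 4 adjusted over the list alone (adjusted p = 0.97), with Cxcr4, the receptor that holds cells in the dark zone, at 0.98 ± 0.23 and Polh at -0.71 ± 0.15. Memory against naive cells gave 2.07 ± 0.21 for Egr1, the same direction, and -1.12 ± 0.23 for Cxcr4, the other direction.

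In all, 1818 genes differed between late and early GC, 798 higher and 1020 lower, and 235 of them by at least 2-fold, of which 138 were higher and 97 lower. The count was 884 without late replicate 1. No batch held both groups, so no within-chip value can be given.

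Early GC cells were set against naive cells, on the same chip, to describe entry into the GC. S1pr2, the receptor that retains B cells in the GC, was higher by 7.18 ± 0.16 (145-fold, adjusted p = 9.67e-12) and was the largest rise by the naming rule. Cell division genes detected on 1 of 3 naive arrays had fitted rises, Birc5 by 6.21 ± 0.37, Plk1 by 5.80 ± 0.21, Cdca3 by 5.76 ± 0.30 and Nusap1 by 5.62 ± 0.21. Pbk was at least 39.2-fold, Clspn at least 31.2-fold and Cdkn3 at least 31.0-fold higher. The 8 largest falls by the naming rule were Ly6d at -6.26 ± 0.19, Plac8 at -6.09 ± 0.35, Plpp3 at -5.96 ± 0.30 (detected on 1 early GC array), Klf2, a transcription factor of quiescence and trafficking, at -5.66 ± 0.16, Arhgef18 at -5.13 ± 0.18, the complement regulator gene Cd55 at -5.13 ± 0.18, Ccr6 at -5.02 ± 0.20 and Adgre5 31.9-fold lower. Fas rose by 3.05 ± 0.19 and Bcl6 by 1.23 ± 0.12, whereas Myc differed by -0.55 ± 0.27 (adjusted p = 0.090).

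All 27 tested members of DNA replication and S phase rose (median 3.18, or 3.12 with members undetected in one group at their bound), among them Lig1 by 4.09 ± 0.12 and Mcm6 by 4.01 ± 0.13, and 20 of 21 members of G2/M and mitosis rose (median 4.47, or 4.17 at the bound), with Prc1 up by 4.91 ± 0.13. The germinal centre programme rose in 11 and fell in 2 of 15 cases (median 1.23, or 1.01 at the bound), with Neil1 at 4.31 ± 0.14 and Ezh2, a histone methyltransferase gene, at 3.68 ± 0.14. Dark zone genes rose in 10 of 14 cases and fell in 1 (median 2.52, or 2.34 at the bound), with Gcsam at least 5.70-fold higher. Its members Foxo1 and Cxcr4 were not higher in early GC (means 10.29 and 9.44) than in naive cells (10.46 and 9.57). The list shares the cell division gene Plk1 with G2/M and Gcsam with the germinal centre programme. These calls are therefore not independent, and the dark zone call does not separate a zone programme from cell division. In hypermutation, class switching and linked repair 11 of 16 rose and 2 fell (median 0.95, or 0.89 at the bound), including the uracil glycosylase gene Ung by 3.02 ± 0.12 and Polh by 2.86 ± 0.15. Oxidative phosphorylation rose in 26 of 33 cases and fell in 1, or 28 and 1 adjusted over the list alone (median 0.70), with Sdhb at 1.37 ± 0.15. The mature naive B cell list fell in 16 and rose in 1 of 19 cases, or 17 and 1 adjusted over the list alone (median -0.94), with Satb1 at -3.21 ± 0.18 and Foxp1 at -2.09 ± 0.15. These 7 lists were also called with an estimated correlation, at adjusted p from 0.0022 to 0.043. The memory B cell list fell in 13 and rose in 3 of 20 cases, or 13 and 4 adjusted over the list alone (median -0.80, adjusted p = 0.0501 with an estimated correlation), with the survival gene Bcl2 at least 13.3-fold lower. B cell receptor signalling fell in 16 and rose in 1 of 24 cases (median -0.60, adjusted p = 0.074 with an estimated correlation), with Nfatc1 at -1.39 ± 0.15 on its brightest probe, against which another of its probes was called the other way. MYC targets and ribosome biogenesis rose in 13 of 23 cases (median 0.54, adjusted p = 0.17 with an estimated correlation), with Ranbp1 at 1.60 ± 0.12. The plasma cell programme went both ways, 6 up and 6 down of 15 (adjusted p = 0.99), with Irf4 at -2.79 ± 0.15 and Slamf7 at 1.26 ± 0.13.

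In total 4808 genes differed between early GC and naive cells, 2386 higher and 2422 lower, 1904 of them by at least 2-fold. Naive replicate 1 stood apart from the other naive arrays, with S100a8 at 10.6 against 4.47 and 4.90 and Cd3e at 8.92 against 5.53 and 5.37, and the count without it was 4483. S100a8 was also detected on all 3 early GC arrays, at a mean of 8.68, whereas Cd3e was detected on 0 of them.

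Late GC cells were compared with the cells labelled memory, on the same chip. The sort of the memory cells is not described, and the signal of markers of other cells on their arrays is taken up below. Rgcc, a cell cycle regulator, was higher in the late GC by 5.51 ± 0.27 (45.6-fold, adjusted p = 2.16e-09), Hmces, which shields abasic DNA sites, by 5.38 ± 0.18 and Plk1, detected on 1 memory array, by 5.15 ± 0.21. Mcm10 was at least 27.3-fold, Clspn at least 24.9-fold, Gh at least 22.6-fold, Gnaz at least 17.4-fold and H1f10, a linker histone gene of a multigene family and so uncertain, at least 16.7-fold higher. Ccr6 stood at -6.92 ± 0.20 (121-fold lower) and Ly6d was at least 88.3-fold lower. Gpr183, the oxysterol receptor that guides B cells to the outer follicle, stood at -6.48 ± 0.20, Klf2 at -6.32 ± 0.16, Pml at -6.21 ± 0.18, Plac8 at -5.69 ± 0.35, Arhgef18 at -5.67 ± 0.18 and the integrin gene Itgb7 at -5.50 ± 0.18. Bcl6 was higher by 2.37 ± 0.12 and Fas by 1.29 ± 0.19. Myc stood at -0.71 ± 0.27 (adjusted p = 0.036), a call lost without late replicate 3 (adjusted p = 0.16), memory replicate 2 (0.12) or memory replicate 3 (0.060) and with the authors' processed values (-0.22, adjusted p = 0.072), without background correction (-0.20, 0.079) and without a filter on dim probes (-0.71, 0.075).

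All 27 S phase genes (median 2.86, or 2.81 at the bound) and all 21 G2/M genes (median 3.18, or 2.88 at the bound) were higher in the late GC than in memory, with Chaf1a at 3.82 ± 0.12 and Lig1 at 3.56 ± 0.12, while Bub1b was at least 17.9-fold and Kif2c at least 13.3-fold higher. The germinal centre programme was higher in 12 of 15 cases and lower in 0 (median 1.87), with S1pr2 at 4.29 ± 0.16, and dark zone genes were higher in 13 and lower in 1 of 14 (median 2.10), with Cdc20 at 4.29 ± 0.22. Hypermutation and repair genes were higher in 14 and lower in 2 of 16 cases (median 0.82, or 0.77 at the bound), with Ung at 2.05 ± 0.12. The memory B cell list was lower in 15 and higher in 2 of 20 cases (median -2.46, or -2.42 at the bound), and the mature naive list lower in 16 of 19 (median -0.88), with Cd55 at -4.31 ± 0.18. These 7 lists were also called with an estimated correlation. The other 4 were not: oxidative phosphorylation higher in 15 of 33, or 14 adjusted over the list alone (adjusted p = 0.18 with an estimated correlation), with Cox5b at 0.89 ± 0.13, MHC class II presentation lower in 8 of 15 (adjusted p = 0.0998 with an estimated correlation), with Ctss at -2.12 ± 0.23, cytokine and costimulatory genes lower in 15 and higher in 7 of 27 (adjusted p = 0.34 with an estimated correlation), with Cd274, which encodes PD-L1, at -2.81 ± 0.12, and myeloid markers lower in 16 of 17 (median -2.90, or -2.57 at the bound, adjusted p = 0.37 with an estimated correlation). Without memory replicate 1, camera gave adjusted p = 0.088 for the cytokine list and 0.052 for MHC class II. In the myeloid list Mpo, a granule enzyme of neutrophil precursors, was at least 7.12-fold lower in the late GC and Camp stood at -3.27 ± 0.53.

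In total 4428 genes differed between late GC and memory cells, 2134 higher and 2294 lower in the late GC, 1656 of them by at least 2-fold. The late-against-memory and early-against-naive comparisons share no array. They had 1634 genes higher in both, where independent lists would share 637, and 1635 lower in both, where 696 would be shared, and 106 genes were called in opposite directions. Across genes their log2 differences correlated at r = 0.83 (Spearman rho = 0.78). An additive effect of array position common to both chips would enter these comparisons with opposite signs, since early GC and late GC lay at different positions. The shared directions argue against it as the cause of the differences called in both, and do not cover a position effect that differs between chips.

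**Figure D3:**
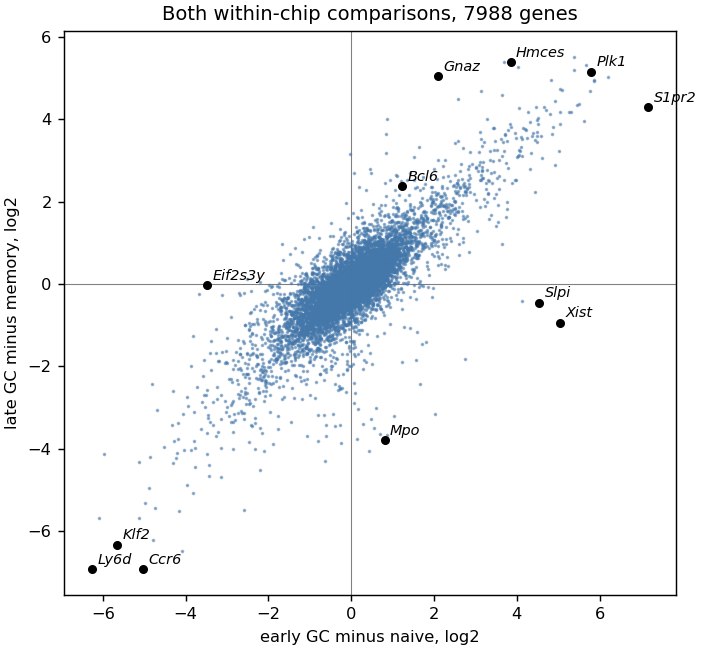
Log2 difference of late GC minus memory against that of early GC minus naive, one point per gene (7988 genes), with 12 genes labelled. Most genes far from 0 lie along the diagonal (r = 0.83 across genes), whereas Xist, Slpi, Mpo and Eif2s3y lie far from it.

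Memory cells were compared with naive cells, as the groups not labelled as GC. Parm1 was at least 59.2-fold higher in memory cells (adjusted p = 4.55e-11), Ighg1, an immunoglobulin constant region gene of a multigene family and so uncertain, at least 30.3-fold and the actin-bundling gene Fscn1 at least 15.5-fold. Fos, an immediate early gene, was at least 16.6-fold higher. The neutrophil granule genes S100a8, S100a9 and Lcn2 were higher by 5.88 ± 1.17, 5.12 ± 0.90 and 4.75 ± 0.71, and by 7.87, 6.63 and 5.81 without naive replicate 1, the only naive array on which they were detected. All these are fitted values and no bounds. Xist, transcribed from the inactive X chromosome, was at least 46.9-fold higher in memory cells and the Y-linked Eif2s3y at least 6.03-fold lower. Among other falls, Plekhg3 stood at -3.83 ± 0.24, Edaradd at -3.20 ± 0.19 (detected on 1 memory array), Il12a, which encodes an interleukin 12 subunit, at -2.51 ± 0.14 and Trps1 at -2.41 ± 0.18, while Diras2 was at least 4.62-fold, Srgap3 at least 4.15-fold and Ube2e2 at least 4.01-fold lower. Fas was higher in memory cells by 2.32 ± 0.19 and Bcl6 lower, at -0.77 ± 0.12, whereas Ccr6 differed by -0.17 ± 0.20 (adjusted p = 0.56) and Myc by -0.33 ± 0.27 (adjusted p = 0.36).

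The memory B cell list was higher in 10 and lower in 3 of 20 cases (median 0.48, adjusted p = 0.0072, and adjusted p = 0.50 with an estimated correlation). Zbtb32, a repressor known from memory cells and detected on 1 naive array, rose by 3.70 ± 0.26 and Zbtb20 by 3.55 ± 0.17, Klf3 stood at -1.89 ± 0.17, and Cd80, a costimulatory ligand, was at least 4.2-fold higher. Without memory replicate 1 another Cd80 probe was the brightest and its difference was 0.34 (adjusted p = 0.31). Immediate early and handling stress genes were higher in 9 and lower in 1 of 14 cases (median 1.25, adjusted p = 0.50 with an estimated correlation), with Egr1 at 2.07 ± 0.21, Fosb at least 5.33-fold and Hspa1a at least 3.15-fold higher. Myeloid markers were higher in 15 of 17 cases and in 16 adjusted over the list alone (median 2.44, adjusted p = 0.73 with an estimated correlation), with Camp at 4.39 ± 0.53, Ngp at 4.06 ± 0.64 and Mpo at 3.31 ± 0.38, each detected on 1 naive array. These 3 lists were the ones called, and camera called 0 of 25 with an estimated correlation, against 11 called by fry. In total 2730 genes differed, 1318 higher and 1412 lower in memory cells, 591 of them by at least 2-fold, and the count without naive replicate 1 was 2602. As these groups lie on different chips, no within-chip value can be given.

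**Figure D4:**
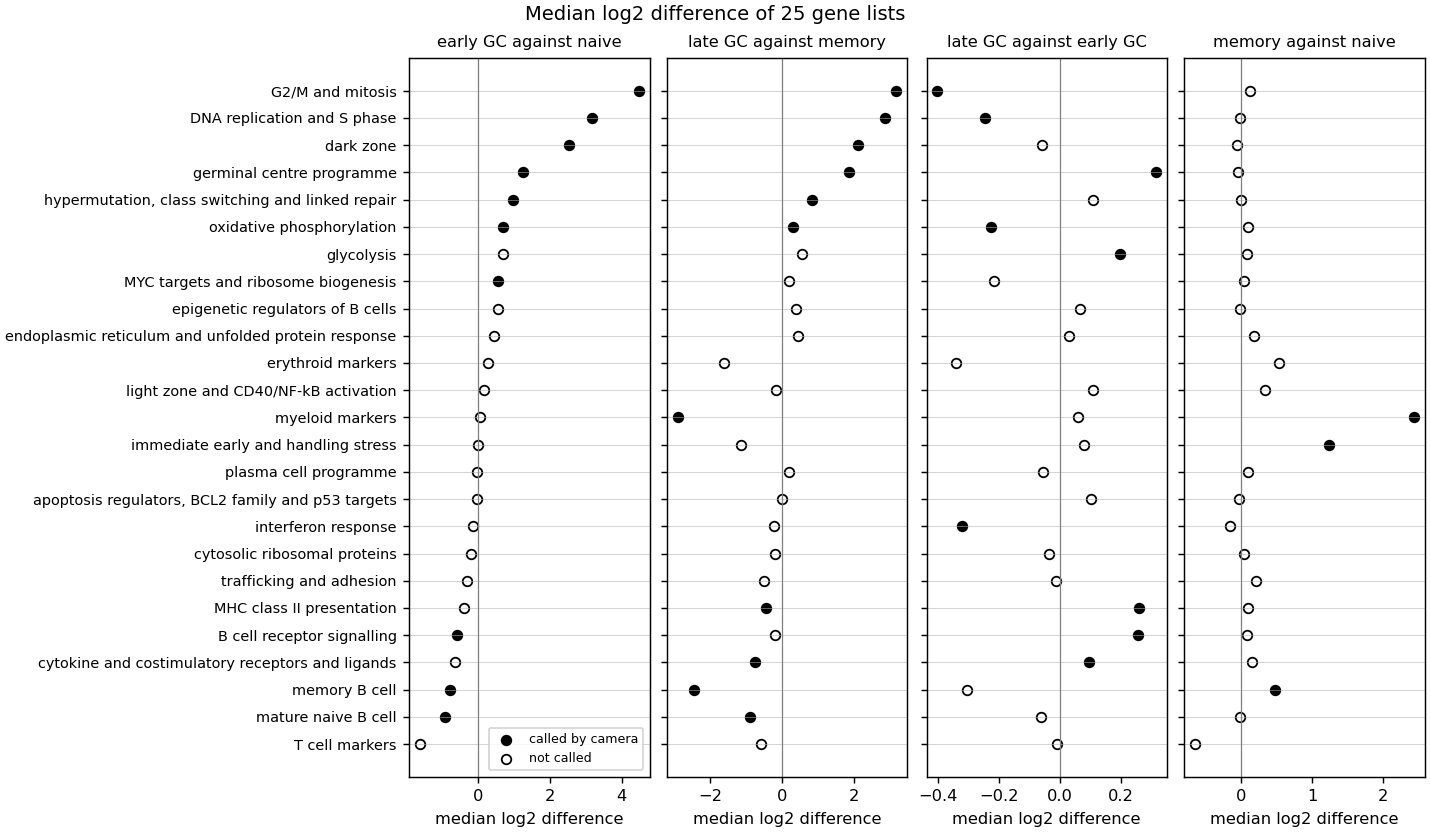
Median log2 difference of the tested members of 25 gene lists in 4 comparisons, with filled points for lists called by camera at a preset correlation, open points for the others and a horizontal scale that differs between panels. S phase and G2/M lists have medians of 3.18 and 4.47 in early GC against naive and of -0.24 and -0.40 in late against early GC.

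**Figure D5:**
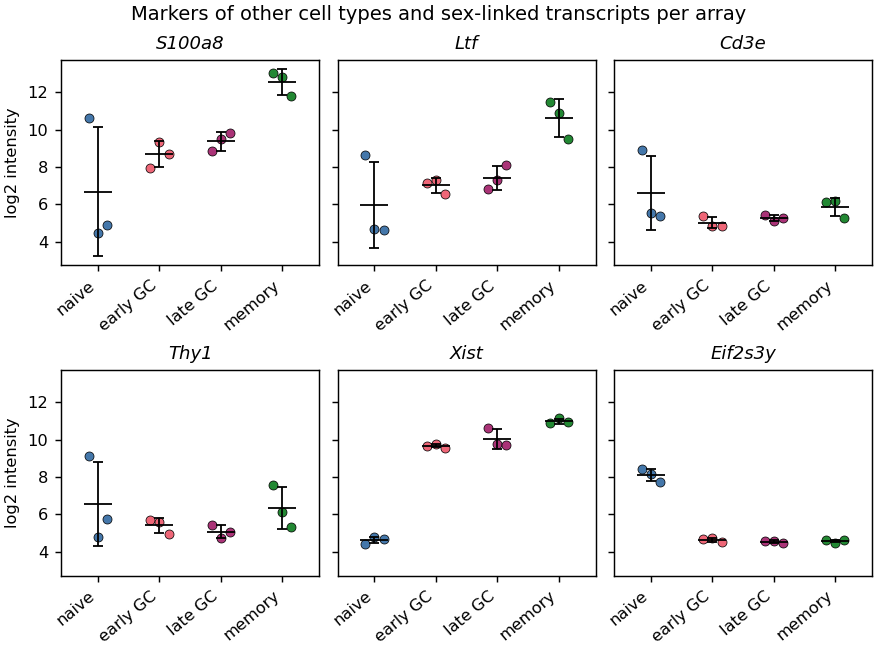
Log2 intensity per array (points) with mean and SD of 3 arrays per group (bars) for the neutrophil genes S100a8 and Ltf, the T cell genes Cd3e and Thy1, and the sex-linked Xist and Eif2s3y. S100a8 is highest in memory cells (mean 12.55), naive replicate 1 is apart from the other naive arrays in the first 4 genes, and Xist and Eif2s3y part the naive group from the other 3 groups.

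The difference between both within-chip comparisons, in which an additive chip effect cancels, was tested as late GC minus memory less early GC minus naive. An additive effect of array position would not cancel in this difference, since naive and late GC shared positions A to C and early GC and memory D to F. The difference of differences is described next. This contrast passed for 1320 genes, 641 positive and 679 negative. Igf2bp3 stood at 3.18 ± 0.34, Gnaz at 2.96 ± 0.38 and Chrna9 at 2.80 ± 0.23, fitted values that are not bounds, since these genes were detected on 0 naive and 0 memory arrays. Bcl6 stood at 1.13 ± 0.16, Fas at -1.75 ± 0.27 and Ccr6 at -1.90 ± 0.29. Memory-associated Zbtb32 stood at -4.09 ± 0.36 and the S phase regulator E2f1 at -1.37 ± 0.20. Of the lists, 6 were called, all negative: myeloid markers, G2/M, immediate early, memory B cell, oxidative phosphorylation and S phase, and 0 with an estimated correlation (lowest adjusted p = 0.41 with an estimated correlation), against 12 by fry. Without memory replicate 1 the immediate early list had an adjusted p of 0.088. The comparisons not described further gave 4730 genes for late GC against naive and 4888 for memory against early GC, both across chips.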

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

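The tests of a chip effect on single probes, of a chip effect on the myeloid markers and both tests on sex-linked transcripts were chosen after the result was seen. The results here drew attention because the late GC and memory pair differed from the early GC and naive pair in a test of the difference itself, or because signal was present in probes that the comparisons did not use.

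The difference of late GC minus memory from early GC minus naive passed for 1320 genes. By the naming rule, its largest positive values were 3.45 for Eif2s3y, 3.42 for Edaradd, 3.18 for Igf2bp3, 3.16 for Fam135a, 2.96 for Gnaz, 2.85 for Srgap3, 2.80 for Chrna9 and 2.64 for Pde2a. Its largest negative values by that rule were -5.99 for Xist, -5.18 for S100a8, -5.00 for Slpi, -4.60 for Mpo, -4.56 for Ighg1, -4.54 for Parm1, -4.51 for Ackr2 and -4.47 for Fos. These are fitted values and no bounds: Eif2s3y and Srgap3 were detected in naive cells only, Fam135a in late GC only, Edaradd on 0 early and late GC arrays, Mpo on 0 late GC arrays, and Xist, Ighg1, Parm1, Fos, Igf2bp3, Gnaz and Chrna9 on 0 naive arrays. The call of S100a8 was lost in 11 of the 12 runs that left out an array, with an adjusted p of up to 0.117 without naive replicate 2. The exception was the run without naive replicate 1, the only naive array on which S100a8 was detected. In the runs that lost the call the fitted value lay between -4.08 (without naive replicate 2) and -5.56 (without memory replicate 3). Fas stood at -1.75, Bcl6 at 1.13 and Ccr6 at -1.90. List medians were -0.35 for S phase, -0.55 for G2/M, -0.74 for immediate early genes, -0.87 for the memory B cell list, -2.53 for myeloid markers and -0.37 for oxidative phosphorylation, all called by camera at the preset correlation. Camera called 0 of them with an estimated correlation (lowest adjusted p = 0.41 with an estimated correlation).

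For the 1320 genes, 6 of 100 splits drawn within chips, the real one included, gave as many, the highest of the others being 2433. The 5 other such splits left naive and early GC arrays in place and exchanged arrays between late GC and memory. They point to a structure of the samples, since they leave the difference between early GC and naive cells in the contrast, so the share does not decide whether chance can be excluded. For each comparison of 3 with 3 arrays, 10 splits of 6 arrays cannot give a share under 0.05. The real split was the 1 of 10 with the most genes in each, at 1818 for late against early GC (highest other 0), 4808 for early GC against naive (1), 4428 for late GC against memory (0), 2730 for memory against naive (2), 4730 for late GC against naive (0) and 4888 for memory against early GC (0).

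Probes without a symbol held signal too. Of 2025 such probes past the detection filter, 411 differed between late and early GC (302 higher and 109 lower in late GC), 1146 between early GC and naive, 957 between late GC and memory and 709 between memory and naive.

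For the genes that differed between late and early GC, an additive chip effect as the whole cause would give memory minus naive, which crosses the same chips, the same size. Turned to the sign of late minus early, its median over the 1818 genes was 0.27 (bootstrap over genes 0.25 to 0.29) against 0.63. The 0.63 is raised because these genes were chosen for passing in that comparison, and memory minus naive also holds differences between those cells. The interval covers the choice of genes and not the spread between arrays. The gap is thus only weak evidence against such an effect as the whole cause. A chip effect that differs between probes cannot be told apart from the groups: the log2 differences of both comparisons correlated at 0.088 over 20529 probes with a detection p of at least 0.05 on all 12 arrays and at 0.32 over the tested genes. Of these, 334 were higher in both (132 from independent lists), 341 lower in both (180) and 115 called in opposite directions (309), as a shared chip effect would also give. A difference between GC stages stays open as well.

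Neutrophil granule genes were higher in memory cells than in late GC cells, on the same chip. The median over 17 myeloid markers was -2.90 for late GC minus memory (bootstrap -3.18 to -1.93, 16 of 17 called), a difference that a chip effect cannot make between groups of 1 chip. These markers are not neutrophil genes alone, since C1qc and Vcam1 are among them. Neutrophils among the cells sorted as memory are a candidate explanation: 12 further neutrophil genes, of 24 listed and 23 on the array, had a median of 1.69 for memory minus late GC (1.07 to 2.11), and 11 of the 12 passed. Among all genes tested, 2294 of 7988 were higher in memory. Testing asked for detection on at least 3 of 12 arrays, so a gene raised on the 3 memory arrays alone could enter, whereas a gene low on all arrays could not. A high median was thus favoured in advance and cannot decide whether neutrophils were present. Levels in memory cells were 12.55 for S100a8 and 11.4 for Pglyrp1, which also reached 10.4 in naive cells, while Trem1 was 0.00 apart. The signal was not confined to memory cells. S100a8 (means 8.68 and 9.39) and Ltf (7.01 and 7.41) were detected on all early and late GC arrays. Both lay between 4.47 and 4.90 on naive replicates 2 and 3. Mpo was detected on 2 early GC and 0 late GC arrays. Neutrophils would not account for the macrophage gene C1qc (7.78 in memory, 4.88 in late GC), Vcam1 (8.71, 5.52) or erythroid Slc4a1 (7.66, 5.59), genes chosen after their values were seen, so other cells, a sort that is not described and expression by memory cells stay open.

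Y-linked Eif2s3y and Kdm5d were detected on all 3 naive arrays and on 0 of the other 9, and Xist on 0 naive and all 9 others. Y-linked Uty, with 4 probes, was detected on 1 naive array and 0 others, and Ddx3y had no listed probe. By Eif2s3y, Kdm5d and Xist, all 12 of 12 arrays have the transcripts that male mice for naive cells and female mice for the others would give, which restates the observation and is no test of it. With early GC at its detection bound, Eif2s3y was at least 5.72-fold lower there than in naive cells on the same chip (log2 -2.52, -2.82 to -2.21), a difference that a chip effect cannot make between groups of 1 chip. Differences from naive cells may hold a part due to the sex of the mice, which the groups do not allow to be separated.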

How the results depend on the processing

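Every alternative here was chosen before the result was seen. Of 5807 values of the named genes, 231 genes by comparison, 5631 kept the side of the threshold and, where called, the direction, 152 lost the call, 23 gained it and 1 reversed: Ptprc in late against early GC was 0.75, and -0.086 with the mean of its probes. The cause was not tested. Of the lost calls, 24 came with the threshold of 0.01 and 42 with the 2-fold minimum, which can only remove calls. Most of these genes were named for large differences or small p-values, which favours keeping the call. Medians over all genes lay between -0.06 and 0.03 under every setting. Every setting started from deposited values that were already quantile normalized, so medians near 0 were favoured by construction. A shift common to most genes could not have shown. A stricter adjusted p of 0.01 gave 738 genes for late against early GC, 1547 for memory against naive and 531 for the difference of differences, fewer by construction. A 2-fold minimum gave 235 genes for late against early GC, 1904 for early GC against naive, 1656 for late GC against memory, 591 for memory against naive, 1952 for late GC against naive, 1980 for memory against early GC and 614 for the difference of differences, again by construction. The other processing alternatives stayed within 1.5 times each count. Leaving out 1 array gave 884 (without late replicate 1) to 1898 genes for late against early GC, 4387 to 4801 for early GC against naive, 3838 to 4471 for late GC against memory, 1894 to 2775 for memory against naive and 917 to 1300 for the difference of differences.

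An estimated correlation left 0 of 9 lists for late against early GC, 7 of 11 for late GC against memory, 0 of 3 for memory against naive, 7 of 15 for memory against early GC and 0 of 6 for the difference of differences. The cause was not tested. Fry, which does not compare a list with other genes, called 19 lists for early GC against naive, 24 for late GC against memory, 11 for memory against naive, 19 for late GC against naive and 12 for the difference of differences. Leaving out 1 array gave 3 (without early replicate 3) to 9 lists for late against early GC, and 4 without late replicate 3.

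The replicate numbers did not pair the arrays: deviations from the group mean correlated between arrays of 1 number at -0.11 to 0.18, with 3 of 18 pairs above 0.1. With the replicate number as a block, 1710 genes passed for late against early GC, 4755 for early GC against naive, 4348 for late GC against memory, 2634 for memory against naive and 1241 for the difference of differences. Signal over background limits the dim genes, since 7988 of 19057 genes with a probe passed the detection filter.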

Other observations

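Single members of lists not described above changed in both within-chip comparisons. Among epigenetic regulators Uhrf1, which maintains DNA methylation in dividing cells, rose by 5.26 ± 0.21 in early GC against naive and by 4.16 ± 0.21 in late GC against memory, Ezh2 by 3.68 ± 0.14 and 3.46 ± 0.14, and the methyltransferase gene Dnmt1 by 2.21 ± 0.16 and 2.03 ± 0.16. The list as a whole was not called (adjusted p = 0.28 and 0.083). The anti-apoptotic Bcl2 was at least 13.3-fold lower in early GC than in naive cells and at least 6.30-fold lower in late GC than in memory, while Bad, which opposes it, rose by 1.47 ± 0.12 and 1.00 ± 0.12. Among trafficking genes Gpr183 stood at -4.09 ± 0.20 and -6.48 ± 0.20 and Itgb7 at -4.16 ± 0.18 and -5.50 ± 0.18. S1pr2, of the same list, went the other way, at 7.18 ± 0.16 and 4.29 ± 0.16. The trafficking list was not called either (adjusted p = 0.093 and 0.060).

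Glycolysis genes went both ways. The glucose transporter genes Slc2a3 and Slc2a1 stood at -2.12 ± 0.13 and -1.46 ± 0.15 in early GC against naive and at -2.59 ± 0.13 and -1.25 ± 0.15 in late GC against memory, whereas the phosphofructokinase gene Pfkp rose by 1.41 ± 0.14 and 2.17 ± 0.14. Of 16 tested members 9 rose and 6 fell in the early comparison, and 10 rose and 2 fell in the late one. In the endoplasmic reticulum list Asns, which makes asparagine, rose by 3.29 ± 0.15 and 2.21 ± 0.15 and the disulfide isomerase gene Pdia4 stood at -2.73 ± 0.15 and -2.43 ± 0.15. The list rose in 9 and fell in 4 of 22 cases in the early comparison and rose in 11 and fell in 5 in the late one.

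Naive replicate 1 differed from the other naive arrays in markers of other cells. Its median over 8 T cell markers was 9.07 against 5.44 and 5.70, and over 17 myeloid markers 6.88 against 4.68 and 4.69. Cd3d stood at 9.03 and Thy1 at 9.11 on that array. Without it 4483 genes differed between early GC and naive cells and 2602 between memory and naive cells.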
